A study of Mus musculus with 6 samples.

How the data were processed

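The data are ATAC-seq profiles of 6 samples of a c-myc-immortalised mouse embryonic fibroblast line, 2 wild-type, 2 Ezh2 knockout and 2 knockout with retroviral Ezh2, with transposition on whole cells, per the labels' protocols. Groups were taken from the genotype and treatment labels. The values used were 1 deposited list of accessible intervals of the Ezh2 knockout. Profiles of the other 2 groups were not analysed here. Bowtie2 2.2.9, deepTools and SEACR, a peak caller for sparse coverage, and the mouse build mm10 are named in the submitters' processing notes, without their order or settings. The calling threshold, any control, the treatment of duplicate reads, any shift of reads for the transposase and how the 2 replicates were combined are not given in the sources used here.

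The list has 6 columns and no header, in the order that SEACR writes. The fourth is read as the total signal of a called region, the area under its coverage, and is a score in the authors' own unit as deposited. The fifth is read as its maximum signal, the height of the coverage, deposited without a stated normalization. The sixth gives the region of maximum. Of 19215 called regions with distinct values, 17067 appear as 1 interval and 2148 as 2 or more intervals that repeat the same values. Of the intervals, 4474 (20.5%) do not contain their own region of maximum. The intervals thus look like pieces of called regions left by an overlap with another interval set, which no source used here describes. Total and maximum signal are therefore summarised per called region and width per interval. Some intervals are very short, 232 of them under 200 bp. The lowest total signal was 15316, which marks the authors' threshold in the list. With no read counts the depth is unknown, and no interval based on depth is given. The exact binomial intervals on shares of genes cover counting over genes only. No value per replicate exists in the list, so Fisher p-values set a gene list apart from other genes within this list alone and say nothing about biological replicates.

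Genes came from a table of RefSeq genes on GRCm38, the assembly behind mm10, with 21887 protein-coding genes on chromosomes 1 to 19, X and Y. The table gives each gene's start and end but no strand, exons or sequence. The plan had assumed transcription start sites, promoter CpG content and motif matching. Promoters were therefore replaced by windows of 1000 bp around both ends of each gene, so an interval at a 3′ end also counts. The analyses by CpG class, matched on CpG content and of motifs, the split into exons and introns, and the mask of unsequenced bases were not run. Random placements used the span between the outermost gene or interval of each chromosome. A gene counted as having an interval where at least 1 bp overlapped a window. Of 519 list entries 514 matched the table, 3 of them by a synonym, and 5 non-coding genes did not.

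Before the data were examined, 24 gene lists and 9 families were fixed, with the rule for named genes. It names Ezh2, with PRC2 summarised; up to 4 members of each described list by total signal and the first 3 in alphabetical order without an interval; the 10 called regions of highest total signal and the 10 widest intervals with their genes, those on unplaced sequence given only as values; every Hox gene; Myc, Cdkn2a, Cdkn2b, Cdkn1a and Trp53; and the 10 genes with the densest distal intervals among those with at least 5 within 50 kb. Some genes that the rule takes are not reported here. The list shares were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 33 tests, at a threshold of 0.05. Direct comparisons of lists, 10 in number, were adjusted in their own family and were chosen after the shares had been seen. Each list was also set against 10000 random lists with the same number of genes per chromosome and, separately, against 10000 drawn from genes within 5 Mb of each member. Both replaced the planned CpG matching and were chosen after the data were seen. Distal intervals within 50 kb of a gene were compared with 10000 random lists matched on 10 bins of gene length. Another 22 families were tested after the data had been seen.

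The alternatives covered windows of 500 and 2500 bp, stricter sets of intervals above the median and above the upper quartile of total signal, an overlap of at least 200 bp, another background, any overlap with a feature, other distances for distal intervals and several settings added later. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9, all random draws with a fixed seed. The code was tested on simulated data. The interval lookup differed from a plain loop at 0 of 400 genes. For the shares of 21887 genes by list, with 20 genes per list, the adjusted Fisher test called 48 of 50 lists simulated at 85%, 43 of 50 at 10% and 1 of 50 left at the share of other genes, about 45%. The chromosome-matched percentile called 49, 48 and 2 of them, and the neighbour percentile the same numbers. For distal intervals around lists, the length-matched percentile called 50 of 50 lists raised 2.5 times and 4 of 50 left unchanged. Simulated lists were scattered at random over the genome, with values independent between genes. These rates therefore need not hold for lists of clustered genes, such as Hox clusters and tandem families.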

Results

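Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in a mouse embryonic fibroblast line immortalised with c-myc. The design had 3 groups with 2 samples each: wild-type cells, cells lacking Ezh2, and Ezh2-null cells given back Ezh2 from a retrovirus. Ezh2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at lysine 27. The series title places the work in the study of transcriptional memory at Polycomb target genes. The values described here come from 1 list of accessible intervals, that of the Ezh2-null cells. The wild-type and rescued cells were not analysed here, so no value below compares genotypes. The list carries no value per replicate, so no replicate error could be given, and the read depth behind it is unknown.

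The Ezh2-null list held 21835 intervals covering 62.8 Mb, with a median width of 2453 bp (quartiles 1854 and 3309 bp). They belonged to 19215 called regions, whose total signal had a median of 29082 (quartiles 20504.5 and 45461.5) and whose maximum signal had a median of 27 (quartiles 18 and 39), both in the authors' units. Gene ends were the feature most enriched over random placement. Of the intervals on the chromosomes, 34.4% had their midpoint within 1 kb of an end of a protein-coding gene, against 3.31% of the same intervals placed at random on the same chromosome, a ratio of 10.4. Inside genes lay 37.5% (39.96% at random) and between genes 28.1% (56.7% at random). Each share lay outside all 1000 random placements (two-sided permutation p = 0.001998, the smallest they can give). An interval stood within 1 kb of a gene end at 10378 of 21887 protein-coding genes (47.4%, exact 95% binomial interval 46.8 to 48.1), and 78.1% of these had it at one end only.

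The genes of the Polycomb complexes themselves were accessible. Ezh2, at 47530274 to 47595270 on chromosome 6 (mm10), had an interval over its upper end at 47593609 to 47596498, with a total signal of 40464 and a maximum of 61. The part of Ezh2 removed in the knockout is not given in the sources used here, so this interval does not check the genotype. Of the 13 genes of PRC2 and its accessory subunits, 11 had a gene-end interval (84.6%, interval 54.6 to 98.1; Fisher's exact test against other genes, adjusted p = 0.0162). The 4 highest total signals were at Epop (204844), Phf1 (166497), Rbbp4 (52045) and Eed (49096), while Phf19 and the X-linked Ezhip had none. Of 20 genes of Polycomb repressive complex 1, which contains the H2A ubiquitin ligases Ring1 and Rnf2, 19 had one (interval 75.1 to 99.9; adjusted exact p = 4.2e-05). Pcgf2 (280999), Cbx8 (274152) and Ring1 (163926) were among the highest by total signal, and Cbx7 alone had none. Trithorax-group and H3K27 demethylase genes, which act against Polycomb, had an interval at 15 of 18 (83.3%, adjusted exact p = 0.00674). Wdr5 (119049), Men1 (93229), Kdm6b (87355) and Arid1a (82909) led there, and Ash2l, Kmt2d and Nsd1 had none. Total signals given for genes, here and below, are those of the whole called region, whose maximum lay outside the interval at the gene for Epop, Phf1, Pcgf2, Neurod2, Fbn1, Ier3, Btg2, Tubb5, Hsp90ab1, Rbfox3, Elf3 and Apob. Epop, Pcgf2 and Cbx8 lie on chromosome 11 beyond 90 Mb, where 77.2% of all genes had an interval. Without the genes of that segment and of chromosomes 5, X and Y, the PRC2 share was 87.5% (adjusted exact p = 0.0447) and the PRC1 share 92.9% (adjusted p = 0.00171). Above the upper quartile of total signal the PRC2 share was 15.4% against 15.9% of other genes (adjusted exact p = 1).

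Genes of transcription factors and signals that are textbook Polycomb targets stood on the other side. Among 59 endoderm and mesoderm regulators 14 had a gene-end interval (23.7%, interval 13.6 to 36.6; 47.5% of other genes; adjusted exact p = 0.00051), and among 50 neural regulators 15 did (30.0%, interval 17.9 to 44.6; adjusted p = 0.0231). The endoderm and mesoderm members with the highest total signal were Sox18 (124141), Fgf8 (97702), the morphogen gene Shh (51779) and Foxf1 (45022), and Alx4, Bmp4 and Cdx2 were the first in alphabetical order without one. The neural members that led were En1 (114162), Emx2 (79730), Neurod2 (75110) and Zic1 (65981), whereas Barhl2 and Dbx1 were among those with none. At Fgf8 and Neurod2 the interval lay beside the gene, within 1 kb. Where a Polycomb target did have an interval, its maximum was low: the median maximum signal was 21 over 29 such genes and 38 over all genes with one, while median total signals were 39500 and 39334.5 (differences not tested). The median maximum was also under 38 over 44 genes of the fibroblast lists (32) and 20 marker genes of other cell types (27.5). The share of Polycomb targets, 29 of 109 (26.6%), lay between that of 69 fibroblast genes (63.8%; adjusted p = 5.48e-06 for the difference) and that of 136 marker genes of other cell types (14.7%; adjusted p = 0.0614, not past the threshold; Fisher's exact tests, 10 comparisons). The neural call was lost among intervals above the median (18.0% against 29.98% of other genes, adjusted exact p = 0.0866) and above the upper quartile of total signal (10% against 15.88%, adjusted p = 0.391), where the shares of both groups fell. The difference from other cell types, 11.9 percentage points, passed the threshold with gene-end windows of 500 bp (adjusted exact p = 0.0211) and with an overlap of at least 200 bp (adjusted p = 0.0305), but was 6.95 points above the median (adjusted p = 0.176) and 1.27 points above the upper quartile of total signal (adjusted p = 0.871).

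Of the 4 Hox clusters, which encode positional homeobox factors and are classical Polycomb targets, HoxB had the highest share of genes with a gene-end interval and HoxD the lowest. HoxB on chromosome 11 (96194316 to 96368254) had a gene-end interval at 9 of its 10 genes, with Hoxb1 the exception, and 14 intervals covered 34.5% of the cluster with 5 kb at either side. A single interval of 15455 bp covered Hoxb9 and nearly all of Hoxb8 and came within 1 kb of Hoxb7 (total signal 169507, maximum 40). HoxD on chromosome 2 (74668225 to 74765142) had 1 interval, of 1600 bp at Hoxd8 (total signal 16817, maximum 18), covering 1.496%, and Hoxd1, Hoxd3, Hoxd4 and Hoxd9 to Hoxd13 had none. HoxB and HoxD differed (9 of 10 against 1 of 9 genes, Fisher's exact test, adjusted p = 0.00364), and the other 5 pairs of clusters did not pass the threshold (lowest exact adjusted p = 0.141). In HoxC on chromosome 15 (102921131 to 103036856), Hoxc4, Hoxc5, Hoxc6, Hoxc8 and Hoxc10 had a gene-end interval, with a called region of total signal 227772 over Hoxc4 to Hoxc6. HoxC was close to HoxB in coverage, with 10 intervals over 29.997% of the cluster with 5 kb at either side. Its highest maximum signal, 40, equalled that of HoxB. Hoxc9, Hoxc11, Hoxc12 and Hoxc13 had no gene-end interval. Hoxc9 did hold an interval inside the gene (2064 bp, total signal 20619, maximum 22), while that of Hoxc10 lay beside the gene, within 1 kb. In HoxA on chromosome 6, 6 of 11 genes had a gene-end interval, among them Hoxa5, Hoxa6, Hoxa10 and Hoxa11, all with total signals of at most 28257. Genes without one included Hoxa9 and Hoxa13. Against other protein-coding genes HoxB was higher (adjusted exact p = 0.0148; 0.0618 with intervals holding their maximum) and HoxD did not pass the threshold (adjusted p = 0.0524; 0.0321 with windows of 2500 bp), and neither did HoxA (0.766), HoxC (0.766) or all 39 Hox genes together (21 with an interval, 0.468). Directions that turned without passing the threshold were those of HoxA above the median (0% against 29.97%, adjusted exact p = 0.0620) and the upper quartile of total signal (0% against 15.9%, adjusted p = 0.333), HoxC with windows of 500 bp and with intervals holding their maximum (44.4%, adjusted p = 1 in both), and all Hox genes outside chromosomes 5, X, Y and distal 11 (41.4%, adjusted p = 0.617). Neighbouring Hox genes share intervals, so the tests count them as more independent than they are. Of the other genes within 5 Mb, 70.3% had an interval around HoxB and 34.3% around HoxD, and HoxB lay at percentile 90.7 and HoxD at percentile 8.32 of random lists drawn from those neighbours.

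**Figure D1:**
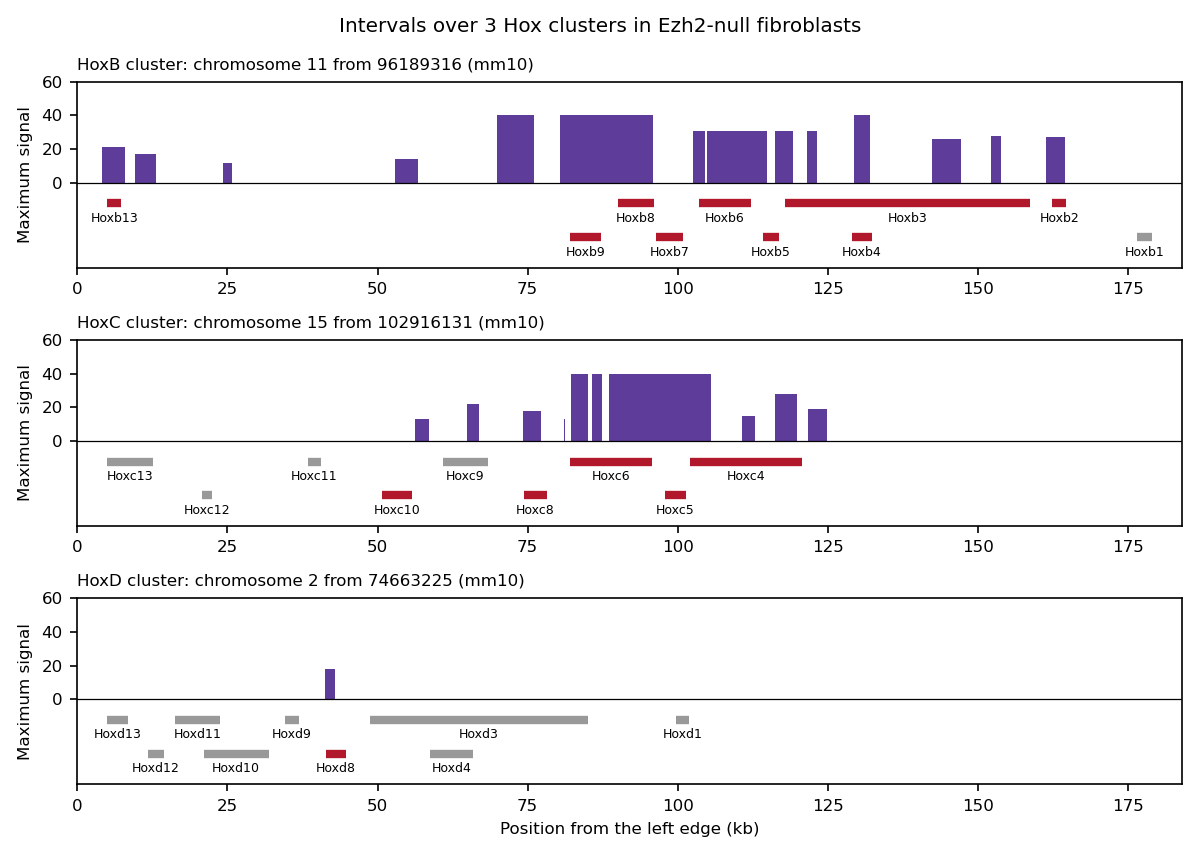
Maps to scale of the HoxB, HoxC and HoxD clusters with 5 kb at either side (position in kb, mm10): bars are ATAC-seq intervals with the maximum signal of their called region as height (authors' units), and lines below are genes, red with and grey without an interval within 1 kb of a gene end. HoxB carries 14 intervals and HoxD 1.

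Genes of 3 fibroblast lists had a gene-end interval more often than marker genes of 7 other cell types (Fisher's exact test, adjusted p = 2.06e-11). The shares were 44 of 69 and 20 of 136, the latter without members of the Polycomb target lists. Of 30 extracellular matrix genes, 21 had an interval (70.0%, interval 50.6 to 85.3; adjusted exact p = 0.0235), led by the collagen genes Col6a1 (144531), Col1a1 (108721) and Col5a1 (105477) and by the fibrillin gene Fbn1 (111805), while Dcn, Fap and Lum had none. This call was lost when 4 families of receptor, keratin-associated and defensin genes were taken out of the background (adjusted exact p = 0.0536). Mesenchymal transcription factor genes (14 of 24, 58.3%, adjusted exact p = 0.355) and smooth muscle genes (9 of 15, adjusted p = 0.468) did not pass the threshold against other genes, and the former stood at 8.33% against 15.9% above the upper quartile of total signal (adjusted p = 0.438). Snai1 (89807), Ebf1 (54782), Prrx1 (52258) and Twist2 (49016) led the former and Cnn2 (297117), Srf (120911), Tpm1 (73831) and Tpm4 (70730) the latter. Meox1, Meox2 and Osr1, and Actg2, Cnn1 and the X-linked Flna, were the first without an interval. Pluripotency and germline genes had an interval at 1 of 22 (4.55%, adjusted exact p = 6.16e-05; Lin28a, 24517), hepatocyte genes at 1 of 19 (5.26%, adjusted p = 0.000288; Apob, 20236), haematopoietic genes at 3 of 24 (12.5%, adjusted p = 0.00146), striated muscle genes at 3 of 19 (15.8%, adjusted p = 0.0104) and epithelial genes at 4 of 20 (adjusted p = 0.022). Endothelial (4 of 17, adjusted exact p = 0.066) and neuronal genes (5 of 19, adjusted p = 0.0826) did not pass the threshold. The members with the highest total signal were Cd68 (108340), Cd79a (34992) and Klf1 (33796) for haematopoietic, Tnnt2 (97729), Casq1 (41387) and Mb (20296) for striated muscle, Spint1 (51436), Elf3 (42938), Cldn4 (31344) and Krt8 (16652) for epithelial, Egfl7 (134441), Sox18, Flt1 (71520) and Eng (70860) for endothelial and Rbfox3 (354291), Grin1 (93933), Slc17a7 (35093) and Gad1 (22153) for neuronal genes. The intervals at Lin28a, Cd79a, Mb, Cldn4, Krt8 and Slc17a7 lay beside the gene, within 1 kb, and not over it. With windows of 500 bp the pluripotency and germline share was 0%. The total signal at Rbfox3 exceeded that of every fibroblast gene named above. It is the sum over a called region whose maximum lay outside the interval at the gene. By maximum signal Rbfox3 (53) was below Cnn2 (65) and above the other fibroblast genes named, of which Snai1 (49) was the highest. Endothelial genes passed with windows of 500 and 2500 bp, an overlap of 200 bp and the reduced background (adjusted exact p = 0.0342, 0.0381, 0.0228 and 0.0370), and neuronal genes with windows of 500 bp and that background (adjusted p = 0.0134 and 0.0482). The endothelial direction turned above the upper quartile of total signal (23.5% against 15.9%, adjusted exact p = 0.391). Above the median total signal the haematopoietic, striated muscle and epithelial calls were lost (12.5%, 10.5% and 10% against 29.97% of other genes, adjusted exact p = 0.0935, 0.0962 and 0.0755), as were those of haematopoietic (4.17%) and striated muscle genes (5.26%) above the upper quartile (adjusted p = 0.241 and 0.391). No epithelial, pluripotency or hepatocyte gene had an interval above the upper quartile, where 15.9% of other genes did, and lists of 20, 22 and 19 genes did not pass the threshold even at 0 (adjusted exact p = 0.09997, 0.0698 and 0.09997). The epithelial call was also lost over the gene body (adjusted exact p = 0.0607).

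All 21 immediate-early genes, which encode AP-1 subunits and other factors induced by growth signals, had a gene-end interval (100%, interval 83.9 to 100; adjusted exact p = 7.3e-07). Ier3 (250103), Egr1 (219034), Zfp36 (180767) and Btg2 (174846) had the highest total signals among them. Myc itself, the gene used to immortalise the line, had an interval at 61985349 to 61988440 on chromosome 15, with a total signal of 157886. Its maximum signal, 169, ranked 2 among 19147 called regions of the chromosomes, and lay inside the gene, 2441 bp from its nearest end. Of 24 genes of the Myc network and its targets 21 had an interval (87.5%, adjusted exact p = 0.000288), with Cdk4 (193222), Myc, Nop56 (134990) and Odc1 (92222) leading and Ldha, Mycn and Tert without. Of 17 genes of the p53, Rb and senescence pathways 14 did (82.4%, adjusted exact p = 0.0105), led by Sesn2 (110140), Bbc3 (90029), Mdm2 (83925) and Bax (82001). The tumour suppressor genes Trp53 (65234), Cdkn2a (56041) and Cdkn2b (35364) each had an interval, and Cdkn1a, Cdkn1c and Pmaip1 had none. Ribosomal protein genes (74 of 83, 89.2%, adjusted exact p = 9.67e-15) and housekeeping genes (21 of 25, 84.0%, adjusted p = 0.00051) were also high. Actb (257731), Tubb5 (250103, in the same called region as Ier3) and Hsp90ab1 (215666) were among the highest of the housekeeping genes, and Psmb4 and the X-linked Hprt were among those with none.

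Genes in tandem families were at the low end, with 7 of 1106 olfactory receptor genes (0.633%, adjusted exact p = 1e-301), 1 of 353 vomeronasal receptor genes (0.283%, adjusted p = 1.37e-96), 0 of 56 keratin-associated protein genes (upper bound 6.38%, adjusted p = 2.87e-15) and 1 of 42 defensin genes (2.38%, adjusted p = 5.34e-10). Genes of tandem families lie side by side in clusters, so tests on them, here and below, count them as more independent than they are. Clustered protocadherin genes had a gene-end interval at 1 of 57 (1.75%, adjusted exact p = 4.41e-14), but 61.4% of them had an interval over the gene body with 1 kb at either side (53.7% of other genes, adjusted p = 0.339). The same interval can count for several genes of a cluster, and the number of intervals behind that share was not counted. Among 19 imprinted genes 4 had an interval (21.1%, adjusted exact p = 0.0305; Gnas, Slc38a4, Igf2r and Dlk1), and Cdkn1c, Grb10 and Igf2 were among those without. That call was lost over the gene body (42.1%, adjusted exact p = 0.411), with intervals holding their maximum (adjusted p = 0.0535) and above the upper quartile of total signal (adjusted p = 0.391). Core histone genes (36 of 58, 62.1%, adjusted exact p = 0.0452) and zinc finger genes named Zfp (214 of 367, 58.3%, adjusted p = 9.66e-05) were higher than other genes. The histone call was lost with autosomal genes alone (adjusted exact p = 0.0802), windows of 500 bp (0.0753) and 2500 bp (0.0584), an overlap of 200 bp (0.0582), the background without 4 families (0.134), gene bodies (0.288) and intervals holding their maximum (0.0605). The Zfp share fell below that of other genes among intervals of above-median total signal (24.8% against 30.0%, adjusted exact p = 0.0456). In all, 12 of the 33 lists and families were higher, 13 lower and 8 not past the threshold. Of the 25 that passed, 24 also lay outside the central 95% of chromosome-matched random lists, the exception being HoxB at percentile 97.475.

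**Figure D2:**
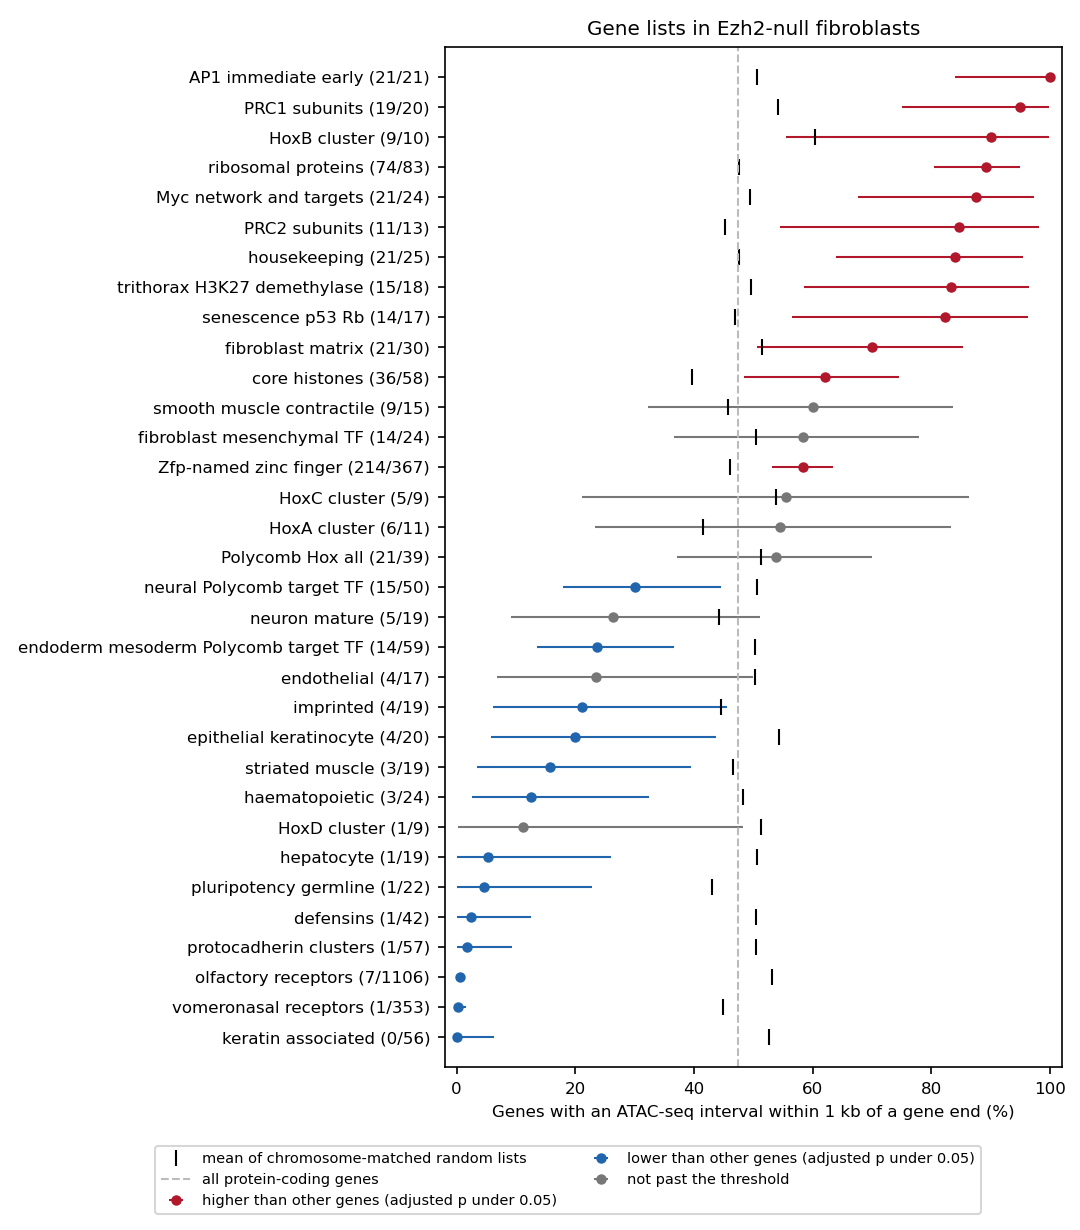
Share of genes (%) with an ATAC-seq interval within 1 kb of a gene end for the 33 lists and families, with exact 95% binomial intervals as bars, genes with an interval and genes in each list in brackets, and the mean of chromosome-matched random lists as black ticks. Points run from 100% for immediate-early genes to 0% for keratin-associated genes, and the dashed line marks 47.4%, the share of all protein-coding genes.

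Intervals at gene ends were wider and stronger than distal ones, which had no gene end within 1 kb. Median widths were 2663 and 2311 bp for 9675 gene-end and 12084 distal intervals. Over their 9185 and 9962 called regions, median total signals were 36084 and 24038, and median maximum signals 36 and 20. An interval counted here by any part within 1 kb of a gene end, not by its midpoint. Wider intervals meet this rule more easily, which favours larger widths and total signals at gene ends. Distal intervals were more numerous around some lists than around random lists and fewer around others. Within 50 kb of matrix genes there were 2.57 on average, against 1.32 for random lists of like gene length (percentile 99.5), and around mesenchymal transcription factor genes 2.79 against 1.495 (percentile 98.2), but around smooth muscle genes 1.53 against 1.33 (percentile 68.1). Immediate-early genes had 2.38 against 1.02 (percentile 99.9) and PRC1 genes 3.05 against 1.37 (percentile 99.4). High percentiles were also found for ribosomal protein genes (1.67 against 0.931, percentile 100), core histone genes (1.09 against 0.362, percentile 99.99), housekeeping genes (2 against 1.1504, percentile 97.9) and HoxC (3 against 1.09, percentile 99.4). Low percentiles were found for Zfp genes (0.749 against 1.31, percentile 0), whose gene-end share was raised, and for olfactory receptor (0.0958 against 0.544, percentile 0), vomeronasal receptor (0.0482 against 0.724, percentile 0), defensin (0.429 against 0.961, percentile 0.63) and keratin-associated genes (0.0893 against 0.337, percentile 1.165). Polycomb target genes lay within the random range, at 0.80 for neural (percentile 8.42) and 0.966 for endoderm and mesoderm regulators (percentile 21.3), but neural regulators fell below it within 100 kb (percentile 1.46) and endoderm and mesoderm regulators above the median total signal (percentile 1.26). Genes of the HoxB cluster had 3.90 and those of HoxD 0 (percentiles 100 and 0.295). The windows of genes within one cluster overlap and count the same distal intervals more than once, while random lists are scattered, so the percentiles of Hox clusters, histone genes and tandem families overstate their independent evidence. When lists were matched also on chromosome, clustered protocadherin genes rose from percentile 96.48 to 100, outside the central 95% of random lists. The mesenchymal factor, PRC1 and defensin values came back inside it (percentiles 97.495, 97.475 and 11.165). So did PRC1 (97.25), housekeeping genes (94.425) and HoxD (2.595) within 20 kb, mesenchymal factors (94.405) and housekeeping genes (95.26) within 100 kb, and, above the median total signal, mesenchymal factors (97.385), core histones (90.9), HoxC (72.0) and HoxD (2.975).

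The called regions of highest total signal on the chromosomes were at Tbc1d16 (119169285 to 119240708 on chromosome 11, total signal 563210 over 12 intervals), at Cdc34 and Gzmm on chromosome 10 (454788) and at Cdc6 and Rara on chromosome 11 (450377). They were followed by regions at Hgs, Mrpl12 and Slc25a10 (439060), Rps21, Cables2 and Rbbp8nl (414785), Samd14 (384079), Fasn and Ccdc57 (380108) and Pip5kl1 and St6galnac4 (368538). The widest single interval, 36181 bp at 180254998 to 180291178 on chromosome 2, lay over Rps21, Cables2 and Rbbp8nl. Among the others were intervals of 35030 bp over the fatty acid synthase gene Fasn, 32692 bp over Cdc6 and Rara, 27937 bp at Chmp6 and 25166 bp over Rfng, Gps1 and Dus1l, all on chromosome 11 beyond 90 Mb. Intervals at Pofut2 on chromosome 10 (24648 bp) and over Psmd3, Csf3 and Med24 on chromosome 11 (22012 bp) came next. The densest distal intervals, per 100 kb within 50 kb of a gene, were around Atg101 (14.1), Tbc1d16 (14.0), Smim41 (13.4), Chrna4 (13.2) and Actb (12.4). Ube2v1, Dnah17, Nptx1, Slc16a3 and Ccdc40 followed, between 12.1 and 11.7.

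Accessibility was spread unevenly over the chromosomes. Chromosome 11 carried 20.01 intervals per Mb and chromosome 5 carried 16.6, against an autosomal median of 7.47, and chromosome X carried 0.791. Chromosome 19 came close to chromosome 5, with 15.6. A gene-end interval was found at 63.2% of 1269 genes on chromosome 5 (interval 60.5 to 65.9), at 60.7% of 705 on chromosome 19 (57.0 to 64.3) and at 60.5% of 1609 on chromosome 11 (58.0 to 62.9). Chromosome 10 followed at 58.9%. Low shares of genes with a gene-end interval were those of chromosome 14 (33.3% of 851, 30.1 to 36.5) and chromosome X (11.9% of 966, 9.93 to 14.1). None of 256 genes on chromosome Y had one. Within chromosome 11 there were 36.7 distal intervals per Mb beyond 90 Mb and 3.11 before it, and 77.2% and 49.8% of genes had a gene-end interval. The ratio of the distal densities, 11.8, was 25.2 above the median total signal and 6.71 with intervals holding their maximum. The segment beyond 90 Mb holds HoxB, Col1a1, Cbx2, Cbx8, Pcgf2, Epop and Rbfox3, among others. The boundary at 90 Mb was chosen after the values had been seen. Leaving out chromosomes 5, X and Y and that segment, 11 lists and families were higher and 13 lower than other genes, and HoxB had no gene left to test.

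**Figure D3:**
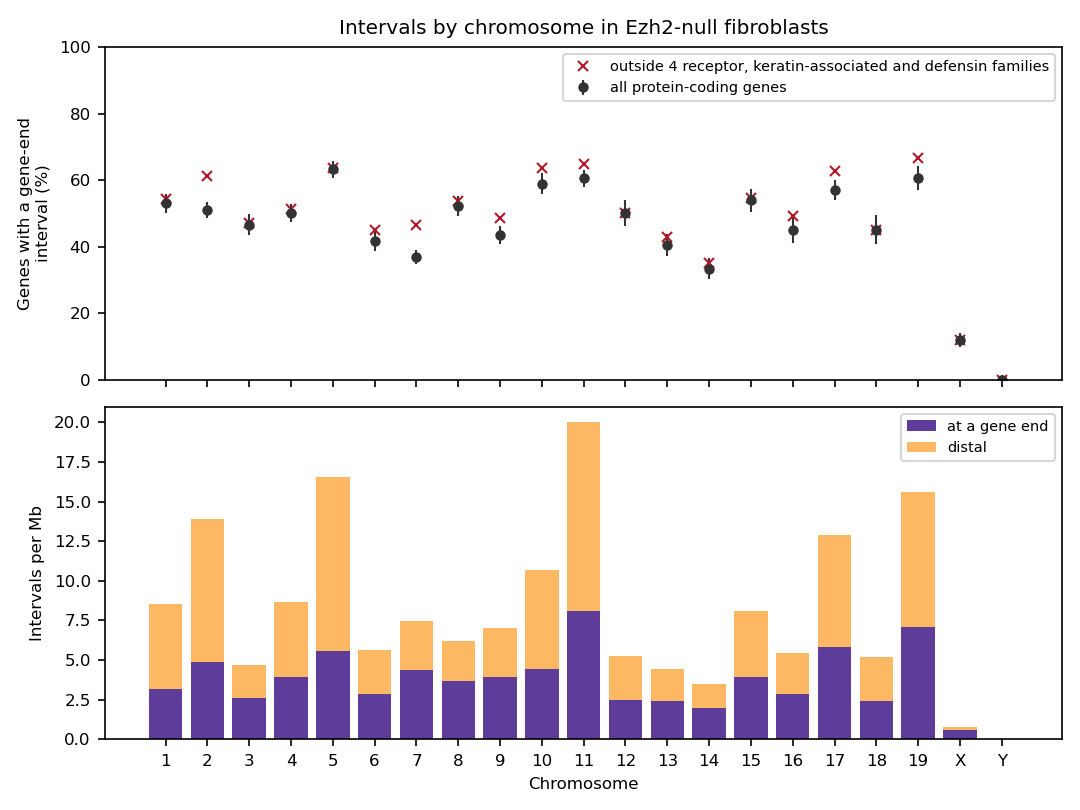
Upper panel, share of protein-coding genes (%) with a gene-end interval on each chromosome, with exact 95% binomial intervals, and crosses for genes outside 4 tandem families; lower panel, intervals per Mb, stacked as gene-end and distal. Chromosome 11 has the highest density at 20.01 per Mb, and chromosome X, at 0.791, the lowest of those with any interval.

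**Figure D4:**
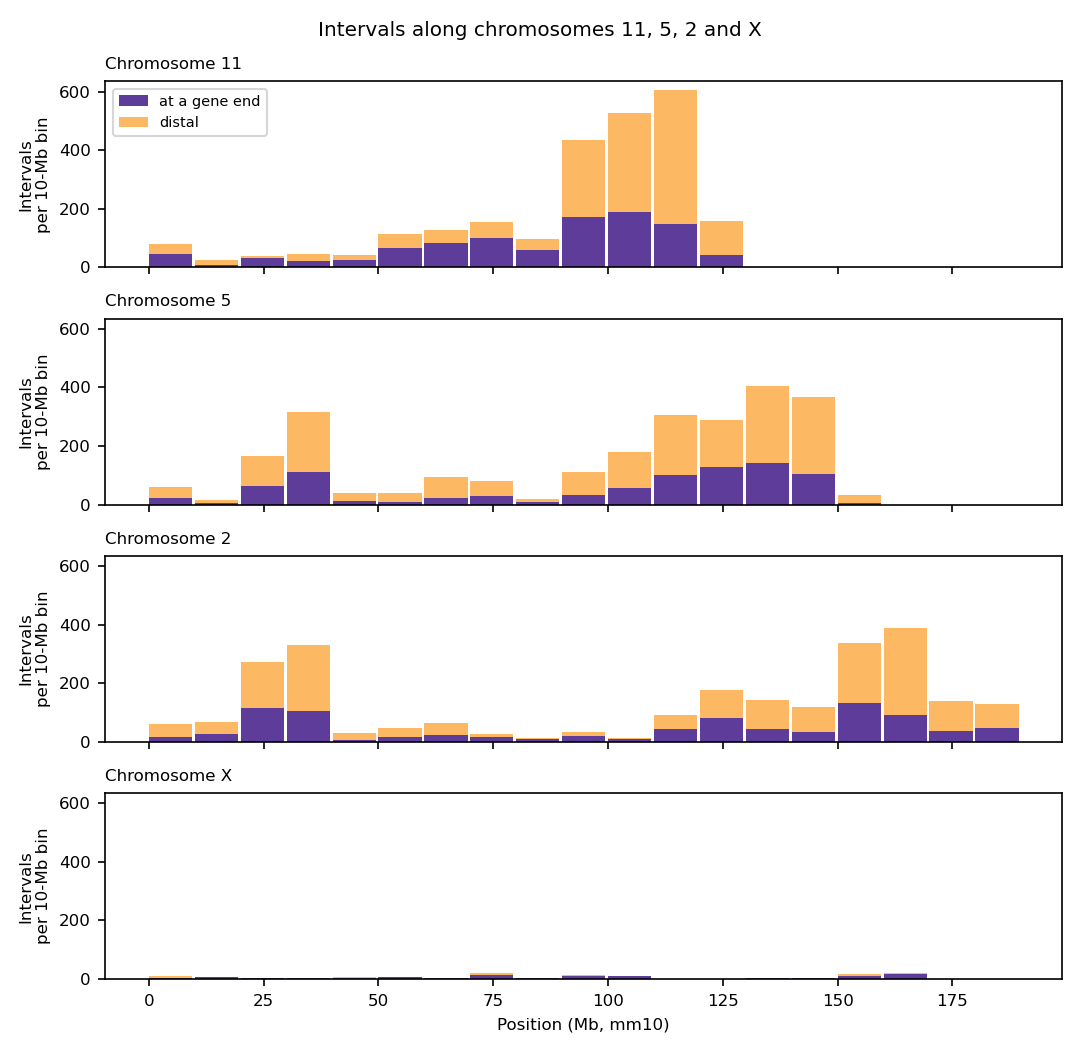
Number of intervals in 10-Mb bins along chromosomes 11, 5, 2 and X (position in Mb, mm10), stacked as gene-end and distal. On chromosome 11 the bin from 80 to 90 Mb holds 95 intervals and the next holds 433.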

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

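All tests of explanations in this part but the one on the calling threshold were chosen after the results they concern had been seen.

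Signal outside the gene comparisons appeared on sequence not placed in the chromosomes, where 76 intervals lay on 17 contigs. The highest maximum signal there was 5412, on an unplaced contig with 114104 bp covered, 29.1 times the highest value on the chromosomes (186).

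Distal intervals were unevenly spread, with more on chromosome 5 and on chromosome 11 beyond 90 Mb and few on chromosome X. Gene density as the whole cause is argued against for chromosome 11, where the ratio of distal intervals beyond against before 90 Mb was 10.0 within 1-Mb bins of like gene number (bootstrap interval 7.87 to 12.9; 11.8 without that grouping, and 25.2 above the median total signal and 6.71 with intervals holding their maximum). The splitting of called regions into pieces is argued against as well, since the ratio over distinct called regions was 8.22 (6.58 to 10.3). Whether more copies of this DNA in the line play a part was not settled. At constitutive genes, which are open in most cell types, the median maximum signal on chromosome 5 and distal chromosome 11 was 1.25 times that on the other autosomes (interval 1.06 to 1.74, 39 and 291 genes). Genes without an interval counted as 0 there, and among those with an interval the ratio was 1.16 (1.01 to 1.60). These segments were chosen for holding many intervals, and 92.3% of their constitutive genes had one, against 80.8% on the other autosomes. That excess enters the ratio of 1.25, which is therefore not separate evidence for more copies. Fewer copies of chromosome X stay open, as only 3 of its 10 constitutive genes had an interval (ratio 0.634), and copy number was not measured; a biological explanation was not tested because no other genotype was analysed here.

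Most HoxB genes and few HoxD genes had an interval at a gene end. The surroundings could account for both: around HoxB 53.6% of 237 runs of 10 consecutive neighbouring genes had as many genes with an interval, and around HoxD 15.3% of 59 runs of 9 had as few. The runs overlap and are not independent. Whether loss of Ezh2 changed either cluster stays open, as the other genotypes were not analysed here.

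The 29 Polycomb target regulator genes with an interval had a median percentile of 50.2 for total signal among all genes with one (bootstrap interval 24.6 to 58.0), so it was not settled whether targets without one lay just under the calling threshold.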

How the results depend on the processing

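No paired analysis was possible because the 1 list analysed here gives no value per replicate, and for the same reason no replicate was left out in turn. Planned settings that need strand, exons or sequence (1 start site per gene, CpG and GC matching, CpG classes and motifs) were not run. Of 455 values recomputed under the settings tried, 358 tested ones kept their direction and their side of the threshold, 23 values or counts without a test of their own stayed within their interval, within 10% or within 1.5 times the main count, 34 fell back across it, 13 newly passed it, 16 moved and 11 turned direction. The cause of each change below was not tested, except that stricter sets and windows hold fewer or more genes by construction. The settings on whole gene bodies, intervals holding their own maximum, autosomal genes, genes outside chromosomes 5, X, Y and distal chromosome 11, chromosome matching and chromosome shares outside tandem families were chosen after the data had been seen. Unknown depth limits every call of absence, since an open site under the authors' threshold is not listed. If the intervals are what an overlap with another interval set left, a called region missing from that set is not listed either.

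The share of all genes with an interval was 45.9% with windows of 500 bp, 50.2% with 2500 bp, 53.7% over gene bodies, 44.96% with intervals holding their maximum, 29.95% above the median total signal and 15.9% above the upper quartile. Windows of 500 bp put HoxC at 44.4%, below other genes without passing the threshold, and Polycomb targets 12.6 percentage points above other cell types, now past the threshold, as did an overlap of 200 bp (13.2), against 6.95 and 1.27 points above the median and the upper quartile of total signal. HoxD, unchanged at 11.1%, passed it with windows of 2500 bp, over gene bodies and without tandem families in the background, where fibroblast matrix genes, at 70.0%, did not. Above the median total signal HoxA was at 0% and Zfp genes at 24.8%, below other genes but past the threshold for Zfp genes alone, and neural targets at 18.0% lost their call, as did haematopoietic (12.5%), striated muscle (10.5%) and epithelial genes (10%). Above the upper quartile, mesenchymal factors (8.33%), PRC2 (15.4%), HoxA (0%) and Zfp genes (8.99%) were below and endothelial genes (23.5%) above the share of other genes, past the threshold for Zfp genes alone, neural targets (10%) and pluripotency genes (0%) lost their call, as did imprinted, haematopoietic, epithelial, hepatocyte and striated muscle genes, and 7 lists were lower. Core histone genes lost their call with both other windows, an overlap of 200 bp, the other background, gene bodies, intervals holding their maximum and autosomal genes. Endothelial genes passed the threshold with both windows, that overlap and that background, and neuronal genes with windows of 500 bp and that background. Over gene bodies protocadherins, which can share an interval within a cluster, were at 61.4% against 53.7% of other genes, not past the threshold. With intervals holding their maximum HoxB (80%) lost its call and HoxC (44.4%) was below other genes, not past the threshold. Without chromosomes 5, X, Y and distal 11 all Hox genes were at 41.4%, below other genes and not past the threshold.

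Gene ends took 44.5% of intervals by any overlap and 38.9% above the median total signal, and exceeded distal regions 1.8 times by maximum signal. The percentile of distal intervals around mesenchymal factors was 94.4 within 100 kb, 97.4 above the median total signal and 97.495 matched on chromosome, all short of the threshold, as were PRC1 within 20 kb (97.25) and matched on chromosome (97.475), housekeeping genes within 20 kb (94.425) and 100 kb (95.26), HoxD within 20 kb (2.595) and above the median (2.975), and core histones (90.9) and HoxC (72.0) above the median. Neural targets passed it within 100 kb (1.46) and endoderm and mesoderm targets above the median (1.26). Genes with an interval made 53.98% on chromosome 5, 1.14% on X and 20.1% on chromosome 6 above the median, and 45.1% on chromosome 6 outside tandem families. The chromosome 11 ratio was 25.2 above the median and 6.71 with intervals holding their maximum.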

Other observations

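Among 22 further gene families, chosen after the data had been seen, 5 were higher and 4 lower than other genes. Intervals stood at 62 of 78 mitochondrial ribosomal protein genes (79.5%, adjusted exact p = 9.09e-08), 47 of 56 translation initiation factor genes (83.9%, adjusted p = 1.48e-07), 40 of 49 genes of respiratory complex I and its assembly (81.6%, adjusted p = 5.55e-06), 40 of 59 Rab GTPase genes, which direct vesicle traffic (67.8%, adjusted p = 0.00748), and 25 of 37 DEAD-box helicase genes (67.6%, adjusted p = 0.0485). The lower families were chemokine genes (4 of 37, 10.8%, adjusted exact p = 1.39e-05), interleukin genes (3 of 31, 9.68%, adjusted p = 4.74e-05), cytochrome P450 genes (6 of 74, 8.11%, adjusted p = 5.75e-12) and orphan receptors named Gpr (22 of 70, 31.4%, adjusted p = 0.0221). The other 13 families did not pass the threshold in Fisher's exact test.

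Myc gave a hypothesis. Its called region had a maximum signal of 169, which was 6.04 times the median of chromosome 15, and the maximum lay inside the gene, 2441 bp from its nearest end. Both tests below were chosen after this had been seen. Other called regions near Myc did not have raised maxima: the median over 5 of them within 500 kb was 0.964 times that of the chromosome (bootstrap interval 0.536 to 1.11). More copies of the chromosomal DNA around Myc were not settled by this. The 5 regions were unmatched and all above the calling threshold, and they cannot show copies of a shorter stretch. Reads from introduced c-myc copies, which an immortalised line of this kind may carry, stay open: of 9184 other gene-end called regions, 6.08% (exact interval 5.60 to 6.58) had their maximum as far from every gene end, above the 5% set as the bound for this explanation.

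Of the 10 called regions with the highest maximum signal on the chromosomes, the first, at 100180069 to 100181017 on chromosome 1 inside Cntnap5b, had a maximum of 186 but a total signal of 34241.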
